A study of Rattus norvegicus with 9 samples.

How the data were processed

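RNA was measured in the whole brain of 9 alcohol-naive male rats, 3 wild type, 3 heterozygous and 3 homozygous for a CRISPR/Cas9 deletion of 618 bp in the long non-coding RNA gene Lrap. Per the labels' protocols, total RNA was purified on silica columns, ribosomal RNA was depleted with Ribo-Zero, stranded TruSeq libraries were made, and 4 libraries shared each lane of an Illumina HiSeq run of paired reads. The wild-type rats were Wistar rats from a commercial supplier, per the labels. Whether they were littermates of the mutants is not given in the sources used here. Which libraries shared a lane is not given in the sources used here.

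The authors deposited RSEM expected counts per locus and per isoform, estimated counts that need not be whole because reads that fit several transcripts are divided between them. They also deposited TPM, which divides each count by the effective length of its transcript and scales each library to the same total, and the percent of a gene's output assigned to each isoform. The deposited tables name loci and isoforms of a StringTie assembly that was merged over the libraries and compared with an Ensembl annotation, per the file contents. Per the submitters' processing notes, the tools were cutadapt, HISAT2, StringTie and RSEM and the build was rn6. Their versions, their order and whether counting used the strand are not given in the sources used here. Reads from a gene and an overlapping antisense gene are therefore treated as uncertain. The build of the reference gene table at hand differs from rn6, so all positions are those of the deposited assembly. For each of the 9 libraries the count table held 0 values that differed from the library's own file. The latter also held 99 loci on spike-in sequences, which stayed out of library sizes and tests.

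Expected counts were rounded to whole numbers. Of 114601 loci, 39057 passed filterByExpr of edgeR 4.0.16 and were tested. Of these, 13360 carried a gene symbol and 22481 overlapped no annotated gene on the same strand. Libraries were scaled with TMM factors and fitted together with edgeR's quasi-likelihood method (robust, with legacy set to FALSE) in R 4.3.3, so that all genotypes shared 1 estimate of the spread. The common biological coefficient of variation was 0.277. Contrasts were homozygous and heterozygous against wild type, homozygous against heterozygous, the slope per deleted allele, and the heterozygous level against the midpoint of the other genotypes. Each adjusted p is Benjamini-Hochberg over the loci tested, with a threshold of 0.05. Isoforms were tested in the same way (63699 isoforms), and isoform usage with diffSpliceDGE and a Simes p per gene (9659 genes). Levels are CPM, counts scaled to a common total by TMM-scaled library sizes, given as mean ± SD, and log2 fold changes carry their standard error (SE).

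Before the data were examined, 40 gene lists were fixed: cell types, brain regions, transmitter systems and cell processes. Of these, 37 had at least 5 tested members and were tested with camera in limma 3.58.1 with its preset correlation. The pineal gland, mitochondrially encoded and nuclear-retained non-coding lists had fewer, and for the pineal list only levels are given. The genes named follow a rule fixed at the same time: Lrap first, then the calls and the 10 symbol genes of smallest p in each comparison where fewer than 10 passed, the 4 members of smallest p of each list past its test, the 10 smallest p among isoforms and usage, and the 6 tested genes nearest Lrap. Some list members that this rule picks are not reported here. Markers of brain regions, libraries and chromosome 12 loci named elsewhere were chosen after their values were seen.

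Library depth ran from 27489383 to 46975919 expected counts. A ratio with 1 to 3 counts in the lower group is given with an exact 95% interval, and a fold against a group at 0 is a bound against a floor of 3 counts over that group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing shows that 2 libraries of a genotype were the same library: over 27227 loci, the chi-square per locus between libraries of 1 genotype was 25.4 or more.

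Each step was tested on simulated counts drawn from the real means and library sizes with 200 loci changed in a graded way over the deleted alleles. For homozygous against wild type over 39057 loci, edgeR recovered 16% of loci with a fold of 2, 79% at a fold of 4 and 98% at a fold of 8, with 12 false calls. In the same simulation DESeq2 made 45 false calls and limma-voom 3. For isoforms (63699) it recovered 0%, 20% and 53% at these folds, with 10 false calls. For isoform usage (9374 genes) it recovered 3%, 12% and 33%, with 24 false calls against 22 true ones.

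Alternatives covered size factors, filters, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, an effective-length offset, the replicate number, a surrogate variable (sva 3.50.0), the compared groups alone and each library left out. Covariates for cerebellum markers and spike-in pattern, loci with a symbol alone, omission of the libraries poor in cerebellum or rich in pineal markers, isoforms counted in every library, and estimated correlation, fry and left-out libraries for heterozygous lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9.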

Results

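The series profiled whole-brain RNA of 9 male Wistar rats to ask how loss of Lrap, a long non-coding RNA of the brain, changes gene expression. The rats were 3 wild types, 3 heterozygotes and 3 homozygotes for a deletion of 618 bp. The labels number them as separate rats. They do not say that the wild types were littermates of the mutants, so line and genotype cannot be separated in any comparison with wild type. Totals were 37738860, 35816231 and 33803445 expected counts in wild-type rats 1 to 3. They were 39804529, 42657594 and 46975919 in heterozygous rats 1 to 3, and 27489383, 43455141 and 46852368 in homozygous rats 1 to 3. The 10 most abundant loci took 45.2 ± 8.82% of counts in wild type, 46.7 ± 8.72% in heterozygous and 51.8 ± 2.86% in homozygous rats (SD, n = 3 each).

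The Lrap transcript that contains the deleted length was low in homozygous rats and intermediate in heterozygous rats. The locus, MSTRG.24458, lies on the minus strand of chromosome 12 at 39008385 to 39023973 (rn6) and was assembled as a pair of isoforms. Isoform MSTRG.24458.1 skips a gap of 618 bp at 39015894 to 39016511, the length the labels give for the deletion, whose position they do not give. All 618 bases lie in exon 2 of isoform MSTRG.24458.2, which spans 39011355 to 39016585, counting exons from the lowest coordinate. Isoform MSTRG.24458.2 was at 2.58, 1.90 and 2.36 CPM in wild-type rats 1 to 3, at 1.01, 1.01 and 1.10 in heterozygous rats, and at 0.265, 0.398 and 0.403 in homozygous rats. The means were 2.28 ± 0.348, 1.04 ± 0.0535 and 0.355 ± 0.0779 CPM (SD, n = 3 each), so that heterozygous rats held 45.6% and homozygous rats 15.6% of the wild-type level. By the authors' TPM these shares were 34.4% and 7.84%.

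Isoform MSTRG.24458.1, which lacks the 618 bases, was at 3.08 ± 0.607, 3.16 ± 0.365 and 3.72 ± 0.873 CPM in the same order, and by TPM at 0.14 ± 0.0346, 0.107 ± 0.0252 and 0.1 ± 0.02. Homozygous rats thus held 121% of its wild-type level by CPM and 71.4% by TPM, with exact permutation p = 0.3 for each. The share of the gene assigned to isoform MSTRG.24458.2 went from 60.3 ± 4.84% in wild type through 40.4 ± 3.08% to 16.6 ± 6.10% in homozygous rats. This isoform usage changed between homozygous and wild-type rats (edgeR diffSpliceDGE, adjusted p = 0.0188). The exact permutation p of the share was 0.1, the smallest that 3 against 3 allows. The adjusted p ranged from 0.000516 to 1 over the alternatives. The call was lost with the legacy method (adjusted p = 1), and without wild-type rat 1 (0.0831), heterozygous rat 2 (0.0546) or homozygous rats 1 (0.135), 2 (0.0569) or 3 (0.108). Tested among 63699 isoforms, isoform MSTRG.24458.2 had a log2 fold change of -2.64 (SE 0.30), ranked 4 by p and did not pass (edgeR adjusted p = 0.17). The whole locus was at 5.36 ± 0.767, 4.20 ± 0.377 and 4.06 ± 0.785 CPM, a log2 fold change of -0.41 (SE 0.22) that did not pass (edgeR adjusted p = 0.545). Heterozygous and homozygous rats held 78.4% and 75.7% of its wild-type level by CPM, and 51.8% and 33.1% by TPM (exact permutation p = 0.1 for each TPM comparison). Lower shares by TPM were not particular to this locus. In homozygous rats MSTRG.24459, on the other strand, was at 139% of wild type by CPM and 78.1% by TPM. Isoform levels here are RSEM's division of reads over shared exons, and MSTRG.24459 overlaps the locus on the other strand (log2 fold change 0.48, SE 0.29, edgeR adjusted p = 0.571). If the gap is the deletion itself, homozygous rats cannot make isoform MSTRG.24458.2, and its change in usage follows from the genotype. Its counts in homozygous rats, and those of isoform MSTRG.24458.1 in wild type, would then come from RNA that the named isoform does not match in full. The isoforms also differ outside the 618 bases. An exon of 7462 bp in isoform MSTRG.24458.1 covers gaps of 470 and 3786 bp in isoform MSTRG.24458.2, and isoform MSTRG.24458.1 reaches further at both ends. Reads from these stretches fit only isoform MSTRG.24458.1. How much of the change in usage concerns the 618 bases alone was not tested.

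**Figure D1:**
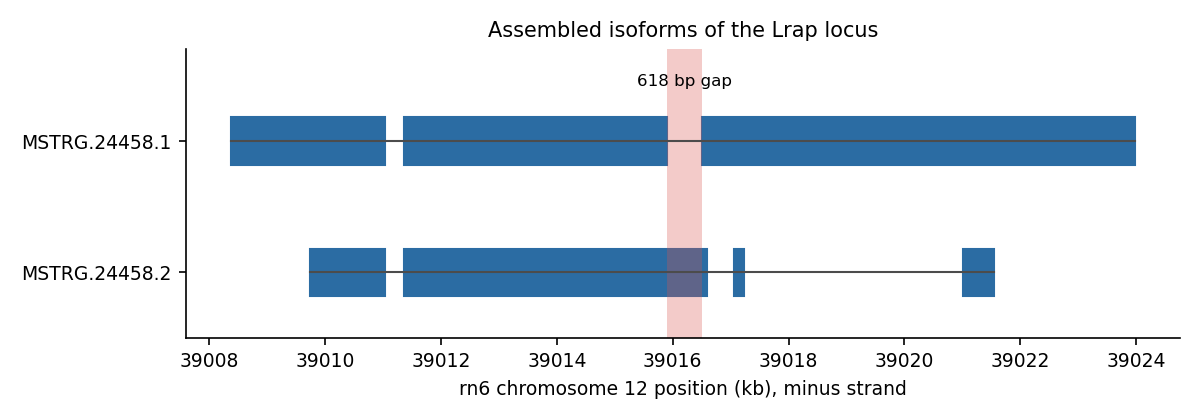
Exons (blocks) of both assembled Lrap isoforms along rn6 chromosome 12 in kb, with the 618 bp gap of isoform MSTRG.24458.1 shaded. The gap lies inside exon 2 of isoform MSTRG.24458.2.

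**Figure D2:**
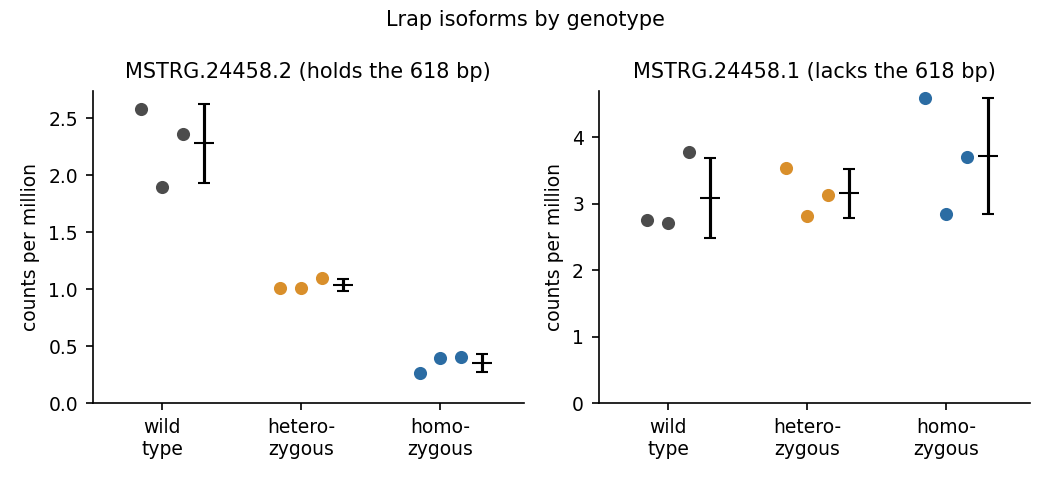
Levels in CPM of both Lrap isoforms in each of 9 rats (points, in order of rat number), with the mean and SD of 3 rats per genotype beside them. Isoform MSTRG.24458.2 has means of 2.28, 1.04 and 0.355 from wild type to homozygous.

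Genes around Lrap were compared to ask whether its neighbours shift with it. The 6 tested genes nearest to Lrap were Orai1 (a calcium channel of the plasma membrane), Morn3, Tmem120b, Kdm2b (a histone demethylase), Rhof and Setd1b (a histone methyltransferase). Orai1 was at 1.12 ± 0.575 CPM in wild-type and 2.01 ± 0.436 CPM in homozygous rats. The log2 fold changes were 0.83 (SE 0.39) for Orai1, -0.15 (SE 0.32) for Morn3, 0.31 (SE 0.27) for Tmem120b, 0.27 (SE 0.21) for Kdm2b, 0.43 (SE 0.22) for Rhof and 0.46 (SE 0.23) for Setd1b. Of 40 symbol genes within 1000 kb to each side, 0 passed by edgeR over all loci, 4 had an unadjusted p under 0.05, and the smallest unadjusted edgeR p was 0.0152. For Morn3, the log2 fold change was 0.15 without wild-type rat 3.

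Homozygous against wild-type rats is the comparison of the deletion on both alleles with none. The 10 symbol genes with the smallest p were all higher in homozygous brains, led by Echs1, a mitochondrial hydratase of fatty acid and valine breakdown, at 9.89 ± 2.70 CPM in wild-type and 27.2 ± 7.28 CPM in homozygous rats. Rn7sl1, the RNA of the signal recognition particle, was at 20600 ± 8030 and 53900 ± 5740 CPM, and Rmrp, the RNA of the ribonuclease MRP, at 625 ± 188 and 2060 ± 963 CPM (SD, n = 3 each). The log2 fold changes were 1.46 (SE 0.25) for Echs1, 1.23 (SE 0.24) for Nudt8, 1.39 (SE 0.26) for Rn7sl1, 1.72 (SE 0.33) for Rmrp, 0.90 (SE 0.19) for Clec2l, 1.49 (SE 0.33) for Igfbp6, 1.76 (SE 0.39) for Shisa3, 0.93 (SE 0.21) for Psd and 0.70 (SE 0.16) for Rplp0, a protein of the ribosomal stalk. Ppp1r35 had 0 counts in each wild-type rat and was at least 15.6-fold higher in homozygous and at least 12.4-fold higher in heterozygous rats. Its level was low throughout, with 42 counts over each mutant genotype (0.450 ± 0.279 CPM in homozygous and 0.322 ± 0.137 CPM in heterozygous rats).

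None of these passed: edgeR called 0 of 39057 loci, and the edgeR adjusted p of these 10 genes ran from 0.288 for Echs1 to 0.544. Over all loci the smallest edgeR adjusted p was 0.0966. The chromosome 12 locus AABR07072283.2, which has no gene symbol, had this value. It was at 3.30 ± 0.310, 7.02 ± 0.634 and 8.98 ± 0.949 CPM from wild type to homozygous. At an unadjusted p under 0.05 there were 3566 loci (1907 higher and 1659 lower in homozygous rats), against 1953 expected by chance. DESeq2 called 33 (26 higher, 7 lower) and limma-voom 0. On simulated counts DESeq2 made 45 false calls beside recovering 46%, 86% and 98% of loci changed by a fold of 2, 4 and 8. How many of the 33 are false cannot be read from the 45, since those arose among many true calls. With edgeR, 1 was called without wild-type rat 1 and 5 without homozygous rat 1. Spike-in proportions followed 1 pattern in wild-type rat 2 and all homozygous rats and another in the other 5 libraries. With this pattern as a covariate, chosen after seeing the data, edgeR called 2189 loci (1614 higher, 575 lower), a fit that by construction sets homozygous rats against wild-type rat 2.

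**Figure D3:**
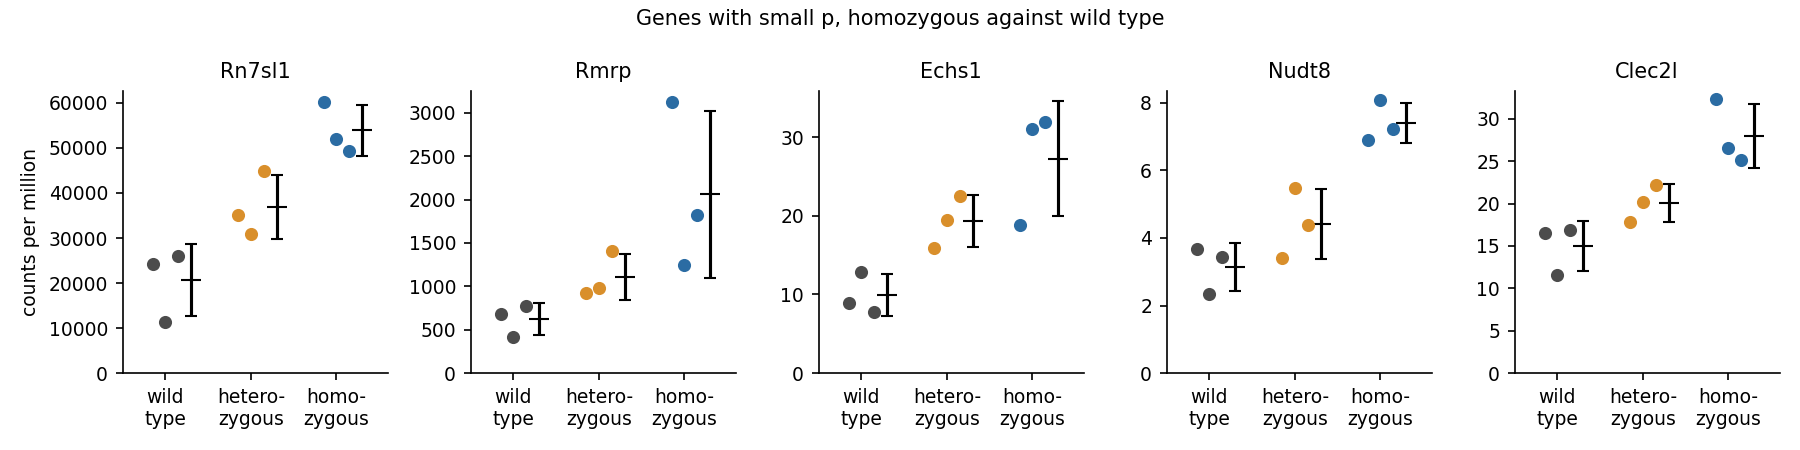
Levels in CPM of Rn7sl1, Rmrp, Echs1, Nudt8 and Clec2l in each of 9 rats (points, in order of rat number), with the mean and SD of 3 rats per genotype beside them. Rn7sl1 has means of 20600, 36900 and 53900 from wild type to homozygous, and none of the 5 genes passed edgeR's test over all loci (edgeR called 0, DESeq2 33 and limma-voom 0, with 3566 loci at an unadjusted p under 0.05).

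Libraries of 1 genotype differed in regional markers. Gabra6, a receptor subunit of cerebellar granule cells, was at 2.30, 4.32 and 103 CPM in wild-type rats 1 to 3, at 15.7, 23.7 and 35.0 CPM in heterozygous rats and at 66.4, 0.585 and 56.8 CPM in homozygous rats. The hypothalamic peptide genes Avp and Oxt were at 0.026 CPM each in wild-type rat 2 and at 1.01 CPM or more in every other rat. Tph1, the serotonin-producing hydroxylase abundant in the pineal gland, was at 90.9 and 92.8 CPM in heterozygous rats 2 and 3 and at 6.62 CPM or less in the others. Mitochondrial transcripts took 27.1 ± 11.6% of counts in wild type, 22.2 ± 6.54% in heterozygous and 16.0 ± 1.06% in homozygous rats. By rat the shares were 21.3, 40.4 and 19.6% in wild type, 23.4, 28.1 and 15.1% in heterozygous and 14.8, 16.9 and 16.4% in homozygous rats, so that wild-type rat 2 stood apart. The exact permutation p of homozygous against wild type was 0.1, the smallest that 3 against 3 allows.

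**Figure D4:**
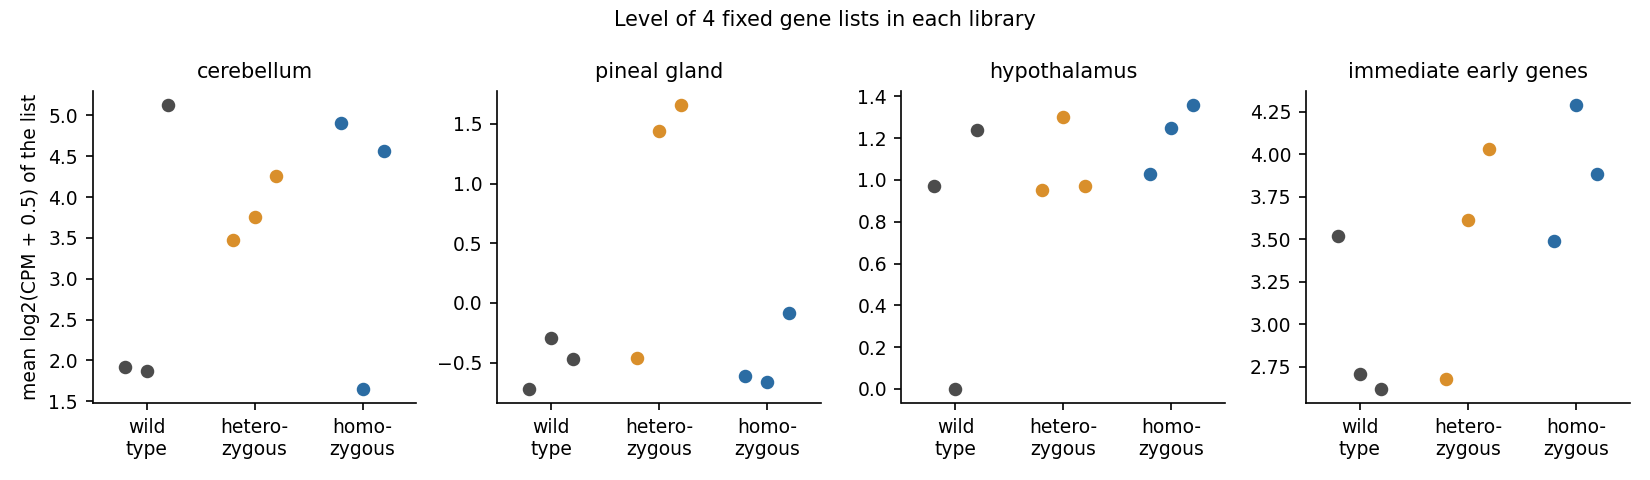
Mean log2(CPM + 0.5) of 4 gene lists in each of 9 rats (points, in order of rat number) by genotype. The cerebellum list runs from 1.65 in homozygous rat 2 to 5.13 in wild-type rat 3, and the pineal list is highest in heterozygous rats 2 (1.44) and 3 (1.66).

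Gene lists were compared between homozygous and wild-type rats to ask which pathways and cell types shift. Each median is over the members' edgeR log2 fold changes, whereas camera tests limma-voom values. Immediate early genes, which neurons switch on with activity, rose as a group: all 18 members were higher in homozygous rats, with a median log2 fold change of 0.98 (camera adjusted p = 4.22e-10; adjusted p = 0.479 with an estimated correlation). The list's mean log2(CPM + 0.5) was 3.52 in wild-type rat 1 and 3.49 in homozygous rat 1, and Egr1 was at 39.5 and 35.2 CPM in these rats. Junb (1.88, SE 0.52), Fosl2 (1.03, SE 0.41), Npas4 (1.20, SE 0.49) and Egr4 (0.92, SE 0.32) had the smallest p. Fos was at 6.46 ± 3.45 CPM in wild-type and 22.2 ± 8.44 CPM in homozygous rats, with 10.4 CPM in wild-type rat 1 beside 13.6 CPM in homozygous rat 1. Of the members, 9 were higher at an unadjusted p under 0.05 and 0 passed by edgeR either over all genes or adjusted over the list alone.

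The blood list fell, with a median log2 fold change of -1.22 over 6 members, all lower (camera adjusted p = 0.000318; adjusted p = 0.479 with an estimated correlation). Its members of smallest p were the anion exchanger Slc4a1 (-1.53, SE 0.53), the neutrophil genes S100a8 (-2.76, SE 0.98) and S100a9, and the haemoglobin gene Hbb (-0.91, SE 0.34). Adjusted over the list alone 3 passed (Slc4a1, S100a8 and Hbb), and over all genes 0 did. Hbb was at 239 ± 114 CPM in wild-type, 126 ± 48.8 in heterozygous and 127 ± 17.1 in homozygous rats.

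In total 29 of 37 lists passed with camera's preset correlation, 28 higher and 1 lower. With an estimated correlation 0 did (adjusted p from 0.479 to 0.755), and by fry 0 did (smallest adjusted p = 0.421). In this comparison symbol genes had a median log2 fold change of 0.16 and all tested loci -0.07. Against symbol genes alone, an alternative chosen after seeing the data, 8 lists passed: immediate early genes, GABAergic neurons, microglia and meninges were higher, and blood, hippocampus, choroid plexus and spliceosome lists were lower, the last with a median log2 fold change of 0.07 that is positive but under that of symbol genes. Wild-type rat 2, the library low in Avp and Oxt and highest in mitochondrial transcripts (40.4%), was the lowest of 9 in 21 of the 29 lists. Outside the 10 most abundant and the mitochondrial loci, 16.2% of its counts lay outside annotated genes, against 7.38 to 12.5% in the other 8 libraries. Without it 13 kept their call and 16 lost it, whereas without wild-type rat 3 all 29 kept it and 24 of their medians were over 1.5 times larger. Medians moved by over 1.5 times in 10 and 21 lists without wild-type rats 1 and 2, and in 3, 7 and 5 without homozygous rats 1 to 3.

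Among cell types, the median log2 fold changes were 0.48 for GABAergic neurons, 0.45 for microglia, 0.44 for meninges, 0.31 for mural cells, 0.24 for astrocytes, 0.22 for endothelial cells, 0.19 for oligodendrocyte precursors (0.29 by limma-voom) and 0.16 for oligodendrocytes (0.25 by limma-voom), all past camera's preset test. For these 8 lists the adjusted p with an estimated correlation was 0.479, except 0.495 for oligodendrocytes and their precursors. The members of smallest p were Cck, Dlx2, Sst and Dlx1 of GABAergic neurons (0.60 to 1.52), C1qc, C1qa, Tmem119 and C1qb of microglia (0.47 to 0.71), Cldn5, Esam, Tie1 and Vwf of endothelium (0.40 to 0.83) and Slc22a6, Islr, Slc6a13 and Col3a1 of meninges (0.71 to 0.80). Those of the glial and mural lists were Aldoc, Gjb6, Fgfr3 and Aldh1l1 (0.42 to 0.57), Cnp, Mbp, Cldn11 and Mag (0.31 to 0.45), Sox10, Neu4, Bmp4 and Olig1 (-0.82 to 0.72), and Tagln, Pdgfrb, Des and Myh11 (0.28 to 0.49). Adjusted over the list alone, Cck, the microglial C1qc, C1qa and Tmem119, and the tight-junction gene Cldn5 passed, and over all genes 0 did. Excitatory neurons (0.20), choroid plexus (-0.43), ependymal cells (0.07) and the pituitary (0.24, with a mean of -0.08, and 0.50 by limma-voom) did not pass. Oligodendrocyte levels, as mean log2(CPM + 0.5), were 7.11, 6.52 and 7.62 in wild-type rats 1 to 3 and 7.38, 7.05 and 7.54 in homozygous rats, and those of their precursors were 3.67, 2.93 and 3.88 against 3.82, 3.64 and 3.88. Without wild-type rat 2 the calls of astrocytes (median 0.13, camera adjusted p = 0.116), endothelium (0.07, 0.36), mural cells (0.07, 0.494), oligodendrocytes (-0.04, 0.744) and their precursors (-0.02, 0.862) were lost, and the median of GABAergic neurons was 0.22 (0.29 without wild-type rat 1). Without homozygous rat 3 those of oligodendrocytes (camera adjusted p = 0.243) and precursors (0.0644) were lost too. Excitatory neurons passed, higher, without wild-type rat 1 (camera adjusted p = 0.00855) or homozygous rat 3 (0.027), and choroid plexus, lower, without the same rats (1.23e-07 and 0.00415). Ependymal cells passed without wild-type rat 3 (0.0281) and the pituitary without homozygous rat 1 (0.0395).

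Among regions, hypothalamus (0.70), cerebellum (0.42), thalamus (0.25) and striatum (0.23) passed camera's preset test and hippocampus (-0.16) did not. With an estimated correlation the adjusted p were 0.479, 0.609, 0.479 and 0.495 for the 4 that passed. By limma-voom the medians were 1.25 for hypothalamus, 0.74 for cerebellum and 0.38 for thalamus, over 1.5 times those by edgeR. The members of smallest p were Cartpt, Gal, Trh and Crh of hypothalamus (0.49 to 0.86), Barhl1, Pcp2, Zic1 and Pvalb of cerebellum (0.39 to 1.28), Ramp3, Cplx1, Gbx2 and Lef1 of thalamus (0.32 to 1.59) and Rarb, Ppp1r1b, Penk and Tac1 of striatum (0.33 to 0.47). Of the transmitter lists, dopamine and serotonin signalling (0.21; Htr1a, Htr2a, Th and Drd3, -0.98 to 1.07), opioid and stress peptides (0.25; Crhr1, Oprd1, Npy2r and Pnoc, -0.55 to 1.07), synaptic scaffold (0.14; Stx1a, Dlg4, Shank3 and Cplx1, 0.39 to 0.59) and voltage-gated channels (0.08; Cacna1i, Cacna1g and Hcn2, 0.50 to 0.57) passed. Their adjusted p with an estimated correlation were 0.495, 0.479, 0.479 and 0.495. GABA-A receptor subunits (0.12) and glutamate receptors (0.06) did not pass. All 8 lists that passed here rested on wild-type rat 2, lowest of the 9 libraries in each but cerebellum. Striatum levels were 3.80, 2.92 and 3.86 in wild-type rats 1 to 3 against 3.62, 3.91 and 3.75 in homozygous rats, thalamus levels 3.89, 3.07 and 4.21 against 3.96, 4.07 and 4.11, and voltage-gated channel levels 6.47, 6.07 and 6.60 against 6.68, 6.44 and 6.51. Without that rat every one of these calls was lost: the medians were 0.14 for hypothalamus (camera adjusted p = 0.354), -0.07 for cerebellum (0.91), -0.08 for thalamus (0.89), -0.04 for striatum (0.571), -0.03 for dopamine and serotonin signalling (0.89), -0.01 for opioid and stress peptides (0.862), 0.04 for synaptic scaffold (0.349) and -0.05 for voltage-gated channels (0.862). The cerebellar call was also lost without wild-type rat 1 (camera adjusted p = 0.502) or homozygous rats 1 (0.542) or 3 (0.835), that of striatum without homozygous rat 2 (0.0943), that of dopamine and serotonin without homozygous rat 3 (0.315) and that of channels without homozygous rat 1 (0.156). GABA-A subunits and glutamate receptors passed without wild-type rat 3 (0.0059 and 0.012) or homozygous rat 2 (0.0166 and 0.0311).

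Lists of metabolism, stress and immunity were compared as well. Nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.26, with 34 of 38 members higher (Ndufs7, Ndufv1, Uqcrc1 and Cox4i1, 0.52 to 1.04), and cytosolic ribosomal proteins 0.21, with 40 of 53 higher (Rplp0, Rpl18 and Rplp2, 0.60 to 0.81). Cholesterol synthesis was at 0.24 (Mvk, Tm7sf2 and Mvd, 0.68 to 0.89), glucocorticoid targets at 0.33 (Mt2A, Per1, Cdkn1a and Dusp1, 0.63 to 1.26), the oxidative stress list at 0.21 (Gpx4, Gstp1, Gpx1 and Prdx6, 0.42 to 0.63) and heat shock at 0.23 (Hspa1b, Hspb1, Dnajb5 and Creld2, 0.34 to 1.06). Immune lists were at 0.33 for MHC (RT1-A2, Tapbp, Psmb9 and RT1-CE10, 0.39 to 0.97), 0.28 for NF-kB (Nfkb2, Myd88, Il1rn and Rela, 0.45 to 1.11) and 0.29 for interferon response (Ifi27, Bst2 and Ddx58, 0.30 to 0.64). The circadian list was at 0.13 (Per1, Nfil3, Cry2 and Cry1, 0.33 to 0.86). All 10 passed camera's preset test. With an estimated correlation the adjusted p was 0.479 except 0.487 for heat shock and 0.508 for interferon. Adjusted over the list alone, Rplp0 of the ribosomal list passed, and 0 members of these lists passed over all genes. Core spliceosome genes (0.07) did not pass, but did without wild-type rat 3 (camera adjusted p = 1.61e-05), homozygous rat 2 (0.00422) or any 1 heterozygous rat (0.0327 to 0.0424). Without wild-type rat 2 the calls of heat shock (median 0.14, camera adjusted p = 0.123) and circadian genes (0.05, 0.36) were lost, and the medians of cholesterol synthesis (0.10), glucocorticoid targets (0.17), NF-kB (0.18) and oxidative phosphorylation (0.16) were smaller by over 1.5 times. Without wild-type rat 1 the medians of oxidative phosphorylation (0.15), ribosomal proteins (0.12) and oxidative stress (0.13), and without homozygous rat 3 that of MHC (0.19), moved as far. The interferon call was lost without wild-type rat 1 (camera adjusted p = 0.382) or homozygous rat 3 (0.315).

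For ethanol and aldehyde metabolism, the pathway closest to the drinking trait in the study's title, the median log2 fold change was 0.24 and the mean -0.02, with 9 of 10 members higher (camera adjusted p = 0.0122; adjusted p = 0.487 with an estimated correlation). Aldh3a1 was at -2.51 (SE 1.02), Aldh7a1 at 0.44 (SE 0.19), Acss1 at 0.34 (SE 0.16) and Aldh2, the main mitochondrial acetaldehyde dehydrogenase, at 0.44 (SE 0.25). By edgeR, 0 members passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. The list's mean log2(CPM + 0.5) was 3.62, 3.40 and 4.34 in wild-type rats 1 to 3 and 3.91, 3.86 and 4.04 in homozygous rats, so that a wild-type rat was highest. Its call was lost without wild-type rat 2 (median 0.08, camera adjusted p = 0.36) and without wild-type rat 1 (0.15, 0.0665).

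Heterozygous against wild-type rats asks whether losing 1 copy suffices. The 10 symbol genes of smallest p were all higher in heterozygous rats, led by the growth hormone gene Gh1 and Ppp1r35, and included Gnb3, Rbp3, Rom1 and Ppef2, which are known from photoreceptors. The log2 fold changes were 3.87 (SE 0.82) for Gh1, 3.59 (SE 0.76) for Gnb3, 6.63 (SE 1.59) for Rbp3, 1.53 (SE 0.39) for Rom1 and 1.66 (SE 0.44) for Ppef2. They were 2.44 (SE 0.60) for the nicotinic receptor subunit Chrnb4, 2.16 (SE 0.54) for the potassium channel Kcnk15, 0.96 (SE 0.25) for Echs1, and 0.85 (SE 0.22) for the matrix protein Fbln1. Rbp3 was at 0.132, 6.12 and 9.93 CPM in heterozygous rats 1 to 3, and at 0.104 CPM or less in wild-type rats, and Gh1 was at 2.00, 0.364 and 0.762 CPM in heterozygous rats. Gnb3 was at 0.659, 6.71 and 8.75 CPM in heterozygous rats 1 to 3 and at 0.444 ± 0.188 CPM in wild type, and Rom1 at 1.63, 4.99 and 5.59 CPM against 1.40 ± 0.196 CPM. None of these 9 genes, nor Ppp1r35, passed (edgeR adjusted p from 0.942 to 0.981).

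EdgeR called 3 of 39057 loci without a symbol, with 1455 at an unadjusted p under 0.05, fewer than the 1953 expected by chance. Locus LOC685025 (MSTRG.109904, chromosome X, 19383844 to 19386581) rose 69.7-fold by counts (95% counting interval 19.0 to 580; edgeR adjusted p = 0.0167) and stood at 50.8-fold (13.7 to 426) in homozygous rats. On chromosome 7, MSTRG.93883 (35623485 to 35626547) had 0 counts in every heterozygous rat and was at least 65.4-fold lower than in wild type (edgeR adjusted p = 0.0028), while MSTRG.93889 (35719751 to 35722833) was at least 61.8-fold higher (edgeR adjusted p = 0.0352). The sum of this pair was 1.47 ± 0.1, 1.56 ± 0.275 and 1.55 ± 0.195 CPM from wild type to homozygous, with all counts at the first locus in wild-type and homozygous rats and at the second in heterozygous rats. The sequences of the pair were not compared, so reads shared between them are not excluded and both calls are uncertain. Each call was tried under 26 alternatives, of which the covariates and the omission of several libraries were chosen after seeing the data, and 2 (a mean of at least 1 CPM, symbol loci alone) did not test these loci. The adjusted p of LOC685025 ran from 0.000206 to 0.789. Its call was lost with limma-voom (0.789) and the spike-in covariate (0.0843), without wild-type rats 1 (0.0761), 2 (0.0809) or 3 (0.0567), without heterozygous rat 2 (0.0626), and without the cerebellum-poor (0.0503) or pineal-rich libraries (0.126). Its fitted log2 fold change was 5.35 to 8.53 in these settings and 5.85 with all libraries. Only wild-type rat 2 of the wild types had counts of it, so without that rat its size depends on the prior count. That of MSTRG.93889 ran from 3.52e-07 to 0.329. Its call was lost with upper-quartile factors (0.112), the replicate block (0.262), the cerebellum (0.0639) and spike-in (0.0843) covariates, without wild-type rats 1 (0.0647) or 2 (0.0809), heterozygous rats 2 (0.0909) or 3 (0.151), and without the pineal-rich libraries (0.329). Its fitted log2 fold change, whose size depends on the prior count because wild-type rats were at 0, was 8.72 to 9.03 in these settings and 8.95 with all libraries. That of MSTRG.93883 ran from 1.14e-07 to 0.126 and was lost without the pineal-rich libraries (0.126, at a fitted log2 fold change of -8.82 against -8.87), which leaves 1 heterozygous rat. With the spike-in pattern as a covariate edgeR called 1 of the 3. DESeq2 called 18 loci and limma-voom 2. EdgeR called 28 without heterozygous rat 1, 7 without homozygous rat 1, and 1 without either wild-type rat 2 or heterozygous rat 2. Among fixed lists, 25 passed camera's preset test, 24 of them higher. Meninges and fibroblasts had the smallest p (median 0.57, camera adjusted p = 9.25e-08, and 0.536 with an estimated correlation). By edgeR median the immediate early genes stood higher, at 0.65. With an estimated correlation 0 lists passed (adjusted p from 0.536 to 0.794), by fry 0 did (smallest adjusted p = 0.752), and without wild-type rat 2 camera's preset test called 12, of which 7 were among the 25, meninges included. In the meninges list Slc22a6, Islr, Slc6a13, Col3a1 and Fmod passed adjusted over the list alone, and 0 members passed over all genes. Gh1 passed adjusted over the pituitary list alone.

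Homozygous against heterozygous rats asks what the second copy adds. Of the 10 symbol genes of smallest p, 7 were lower in homozygous rats: log2 fold changes were -6.35 (SE 1.16) for Gh1, -3.06 (SE 0.74) for Gnb3, -5.14 (SE 1.39) for Rbp3, -3.35 (SE 0.99) for Gngt2, -2.58 (SE 0.72) for Neurod4, -1.89 (SE 0.58) for Chrnb4 and -0.74 (SE 0.21) for Ybx1-ps3. They were 0.93 (SE 0.20) for the zinc-finger gene Zfp14, 1.66 (SE 0.45) for Muc1 and 1.27 (SE 0.35) for Plekha4, and none of the 10 passed (edgeR adjusted p = 1). In heterozygous rats 1 to 3, Gngt2 was at 0.0879, 2.63 and 3.55 CPM and Neurod4 at 0.264, 2.89 and 2.71 CPM. Gnb3, Rbp3 and Chrnb4 were likewise highest in heterozygous rats 2 and 3, the libraries at 90.9 and 92.8 CPM of pineal Tph1. By counts, Gh1 was 109-fold higher in heterozygous than in homozygous rats (95% counting interval 19.2 to 4330). Only MSTRG.93883 was called of 39057 loci by edgeR, at least 68.8-fold higher in homozygous rats (edgeR adjusted p = 0.00255), and 667 loci had an unadjusted p under 0.05, fewer than the 1953 expected by chance. This call is uncertain for the reason given above. In heterozygous rats the counts lay at MSTRG.93889 instead, and the sum of both loci was 1.56 ± 0.275 CPM in heterozygous and 1.55 ± 0.195 CPM in homozygous rats. The edgeR, DESeq2 and limma-voom adjusted p of MSTRG.93883 ran from 1.26e-07 to 0.0321 over the alternatives that leave more than 1 heterozygous rat. Without the pineal-rich libraries, which leaves 1 heterozygous rat, its fitted log2 fold change was 8.91 against 8.94 with all libraries. This size depends on the prior count because heterozygous rats were at 0. DESeq2 called 6 and limma-voom 2. All heterozygous libraries had the other spike-in pattern than all homozygous ones, and with the pattern as a covariate, estimated from the wild-type rats, edgeR called 5. EdgeR called 18 without heterozygous rat 1, and 2 without any 1 of the 3 wild-type rats, heterozygous rat 3 or homozygous rat 1.

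The number of deleted alleles was fitted as a slope to ask which genes follow allele dose. Echs1 led again, at 9.89, 19.3 and 27.2 CPM with 0, 1 and 2 deleted alleles, and Rn7sl1 stood at 20600, 36900 and 53900 CPM. Log2 slopes per allele were 0.73 (SE 0.13) for Echs1, 0.62 (SE 0.11) for Nudt8, 0.86 (SE 0.16) for Rmrp, 0.69 (SE 0.13) for Rn7sl1, 0.45 (SE 0.09) for Clec2l and 0.35 (SE 0.07) for Rplp0. They were 0.30 (SE 0.06) for Sergef, 0.47 (SE 0.10) for Psd, 0.72 (SE 0.15) for the neuropeptide gene Nmb and 0.39 (SE 0.09) for Rtn2. EdgeR called 0 of 39057 loci (smallest edgeR adjusted p = 0.302, 0.324 for Echs1), with 4261 at an unadjusted p under 0.05 against 1953 expected by chance. DESeq2 called 41 (39 higher, 2 lower) and limma-voom 0, and edgeR called 1 without wild-type rat 1 and 3 without wild-type rat 2.

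Fold changes of both mutant genotypes against the shared wild types had a Pearson r of 0.670 across 39057 loci, which are not independent replicates. Simulations redrew all 9 libraries from pooled means with no change between genotypes, each locus on its own. They gave a mean r of 0.497 and a highest r of 0.514 over 100 simulations. The observed covariance was 0.145 against 0.087 simulated, a difference of 0.0581. The same sign was shared by 79.3% of loci against 66.6% simulated. With 3 wild-type rats the controls could not be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. Real loci moved together between libraries, as the cerebellum markers did, and the simulated loci could not. The simulated r may therefore vary too little, and the excess is no evidence of an effect shared by both mutants.

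Whether heterozygous rats depart from the midpoint of the other genotypes was tested directly. Several genes of smallest p, known from photoreceptors, were highest in heterozygous rats 2 and 3: Pde6g was at 0.395, 16.7 and 20.7 CPM in heterozygous rats 1 to 3, against 0.435 ± 0.198 in wild type and 0.545 ± 0.532 in homozygous rats. Log2 departures were 5.11 (SE 0.78) for Gh1, 3.32 (SE 0.58) for Gnb3, 5.89 (SE 1.13) for Rbp3, 2.16 (SE 0.47) for Chrnb4, 2.5 (SE 0.57) for Neurod4, 3.40 (SE 0.77) for Gngt2, 1.32 (SE 0.32) for Rom1, 4.66 (SE 0.98) for Pde6g, -0.67 (SE 0.17) for Zfp14 and 1.38 (SE 0.36) for Ppef2. None passed (edgeR adjusted p from 0.121 for Gh1 to 1). Of 39057 loci edgeR called 2, MSTRG.93883 and MSTRG.93889, the uncertain pair above, with 594 at an unadjusted p under 0.05, fewer than the 1953 expected by chance, while DESeq2 called 12 and limma-voom 2. EdgeR called 40 without heterozygous rat 1, 1 without heterozygous rat 3 and 4 without homozygous rat 3. The call of MSTRG.93889 (adjusted p from 1.8e-14 to 1 over the alternatives) was lost with the replicate block (0.0898) and the spike-in covariate (1), without heterozygous rat 3 (0.0527) and without the pineal-rich libraries (0.146), at fitted log2 departures of 8.72 to 9.03 against 8.95 with all libraries. With the spike-in covariate edgeR called 3 loci, all lower, 1 of them shared. The adjusted p of MSTRG.93883 ran from 2.8e-08 to 0.0166 over the alternatives that leave more than 1 heterozygous rat. Without the pineal-rich libraries, which leaves 1 heterozygous rat, its fitted log2 departure was -8.86 against -8.9 with all libraries.

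Isoforms were compared because the deposited assembly resolves splicing. Mprip isoform MSTRG.15217.3 (a myosin phosphatase partner) was at 24.3 ± 5.74, 6.86 ± 0.946 and 4.24 ± 1.47 CPM from wild type to homozygous, and isoform MSTRG.98516.3 of the sodium channel Scn8a at 7.02 ± 1.66, 11 ± 0.771 and 20.7 ± 3.13 CPM. A Wnk3 isoform (MSTRG.110005.6) was at 4.56 ± 1.21 CPM in wild type and had 0 counts in all mutant rats, and a Celf1 isoform (MSTRG.67116.10) was at 2.83 ± 0.860, 3.38 ± 1.57 and 0 CPM. Isoforms at 0 in wild type were of Ston2 (31.2 ± 15.4 CPM in homozygous rats), Pxn (5.30 ± 1.37), Tmem248 (1.89 ± 0.990) and Man2c1 (1.79 ± 0.791), and those of Tns1 (10.4 ± 8.78) and Kcnh7 (2.98 ± 0.804) were at 0.0169 and 0.0167 CPM. EdgeR called 0 of 63699 isoforms (smallest edgeR adjusted p = 0.0585), with 4403 at an unadjusted p under 0.05, and limma-voom called 0. Without wild-type rat 2 edgeR called 5 and without homozygous rat 2 it called 1.

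DiffSpliceDGE called changed isoform usage in 63 of 9659 genes, Lrap among them, with 809 at an unadjusted p under 0.05. On simulated counts it recovered 33% of genes changed by a fold of 8 and made 24 false calls, so many of the 63 may be false. The leading isoform's share was higher in homozygous rats in 37 genes and lower in 26, by a median of 11.4 percentage points, and in 54 the heterozygous share lay between. Since the genes were selected for a difference between homozygous and wild-type rats, the 54 are no test of allele dose. Osbp2, a sterol-binding protein, went from 2.5 ± 4.29% through 31.5 ± 12.6% to 55.0 ± 9.99%, the focal adhesion gene Pxn from 0 to 37.3 ± 12.5%, Fry from 2.69 ± 4.62% to 28.9 ± 11.2% and the kinesin gene Kif1b from 2.07 ± 2.37% to 15.4 ± 5.48%. The other named genes were Mprip, which went from 3.64 ± 1.60% to 0.497 ± 0.185%, Egfem1, from 7.27 ± 6.44% to 0.02 ± 0.0265%, Ddr1, from 0 to 15.0 ± 11.6%, Kcnh7, from 0.0533 ± 0.0924% to 9.39 ± 1.57%, Fam53c, from 0 to 4.45 ± 1.45%, and Lcorl, from 0 to 2.33 ± 2.25%. Their edgeR adjusted p ran from 2.64e-06 for Egfem1 to 0.0034. The Egfem1 share was 12.2, 9.58 and 0% in wild-type rats 1 to 3 and 0.01, 0.05 and 0% in homozygous rats, so that the groups overlap. Tested as an isoform, it did not pass (edgeR adjusted p = 0.68). Isoforms at 0 in a whole genotype may also reflect RSEM's division of reads over shared exons, which was not tested. In 50 of the 63 genes some library had 0 counts of the leading isoform, and with isoforms counted in every library, an alternative chosen after seeing the data, 11 genes passed, 6 of them shared. The count was 168 without wild-type rat 3 (44 of the 63 among them), 55 without wild-type rat 2 (32 shared), 40 without wild-type rat 1 (20 shared) or heterozygous rat 2 (35 shared), and 33, 39 and 34 without homozygous rats 1, 2 and 3 (19, 26 and 19 shared). The legacy method called 64 genes, of which 33 were among the 63, and the replicate block 74, of which 47 were.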

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

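The values here, and the covariate fit made from them, were chosen only after the data were seen. The 9 libraries' own files hold counts on synthetic spike-in RNAs, which entered no planned comparison and which stand above the limit that a count of 0 allows: they made up from 2.5% to 4.81% of all counts. Their proportions fell into a pair of patterns: the ratio of ERCC-00130 to ERCC-00002 was 1.80 or more in wild-type rats 1 and 3 and all 3 heterozygous rats, and 0.378 or less in wild-type rat 2 and all 3 homozygous rats. Among 39 spike-in species with at least 100 counts in every library, shares in the first pattern differed from the second by log2 values that ran from 2.18 for ERCC-00092 to -1.05 for ERCC-00160. The pattern separates heterozygous from homozygous rats completely, and wild type alone holds both patterns. With the pattern as a covariate, edgeR called 2189 loci for homozygous against wild type and 5 for homozygous against heterozygous rats. The differences were not spread evenly but fell into separate groups: from 1.72 to 2.18, from -0.11 to 0.11, and from -0.5 to -1.05. The spike-ins are synthetic RNAs, so their proportions are not expression of the rats' own genes. What sets the pattern was not tested, and the labels give no spike-in mix or batch.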

How the results depend on the processing

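The settings on heterozygous lists, cerebellum, pineal and spike-in libraries, symbol loci and isoforms counted in every library were chosen after seeing the data. The causes of changes were not tested, except where fewer loci or libraries entered by construction. Without the cerebellum-poor libraries 1 wild-type rat is left, and without the pineal-rich ones 1 heterozygous rat, each assumed to vary like the other groups, so those counts say little of stability.

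For homozygous against wild type (0 called), edgeR called 6 loci with no filter, 1 with the replicate block, 5 with a surrogate variable, 4 with the cerebellum covariate and 5 without the 3 cerebellum-poor libraries, and DESeq2 33. With the spike-in pattern as covariate it called 2189 (1614 higher, 575 lower), which by construction sets homozygous rats against wild-type rat 2. Leaving out each library gave 0 to 5. The loci called in comparisons with heterozygous rats were not tested at a mean of 1 CPM or among symbol loci. For heterozygous against wild type (3), the counts were 5 with no filter, 0 at a mean of at least 1 CPM, 18 with DESeq2, 5 with the length offset, 7 with the compared groups alone, 0 with symbol loci, 1 with the spike-in covariate, 14 without cerebellum-poor and 0 without pineal-rich libraries, and 1 to 28 leaving out each library. For homozygous against heterozygous (1), they were 2 with each of RLE factors, no filter, limma-voom, the length offset, the replicate block and the compared groups alone, 0 at a mean of 1 CPM, 6 with DESeq2, 0 with symbol loci, 5 with the spike-in covariate, 7 without cerebellum-poor and 0 without pineal-rich libraries, and 1 to 18 leaving out each library. For allele dose (0), they were 41 with DESeq2, 1 with the spike-in covariate, 2 without cerebellum-poor libraries and 0 to 3 leaving out each library. For the midpoint (2), they were 5 with no filter, 0 at a mean of 1 CPM, 12 with DESeq2, 4 with a surrogate variable, 0 with symbol loci, 3 with the spike-in covariate (1 shared), 9 without cerebellum-poor and 1 without pineal-rich libraries, and 1 to 40 leaving out each library. For isoforms (0), they were 7 with no filter, 1 at a mean of 1 CPM and 0 to 5 leaving out each library. For isoform usage (63), they were 97 at a mean of 1 CPM, 39 with a share of at least 5%, 11 with isoforms counted in every library and 33 to 168 leaving out each library. Between 19 and 46 of the 63 were called again with a library left out, 33 by the legacy method and 42 at a mean of 1 CPM. For gene lists (29), they were 0 with an estimated correlation, 0 by fry, 16 at a mean of 1 CPM, 8 against symbol loci and 13 to 33 leaving out each library, where the fewest of the 29 were kept without wild-type rat 2 (13) and homozygous rat 3 (24). For gene lists of heterozygous against wild type (25), they were 0 with an estimated correlation, 0 by fry and 12 to 34 leaving out each library, where the fewest of the 25 were kept without wild-type rat 2 (7).

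The log2 fold change of Morn3 ran from -0.30 to 0.15 leaving out each library and reversed to 0.15 without wild-type rat 3. Of the other values of named genes, 819 alternatives gave the same side of the threshold, 41 passed it and 18 lost it. The Lrap isoform stood at 7.84% of wild type in homozygous and 34.4% in heterozygous rats by TPM, and the correlation of both mutants' fold changes was 0.775 at a mean of at least 1 CPM.

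Whether rat numbers mark pairs or batches is not settled. Deviations of the 9 same-number pairs correlated from -0.177 to 0.453, 6 above 0.1, and those of different-number pairs from -0.574 to 0.407. Of 9 libraries, 5 correlated best with a library of their own number. Beside the counts above, the replicate block gave 3 loci for heterozygous against wild type (2 shared, with MSTRG.93889 lost), 0 for allele dose, 2 for the midpoint (1 shared, with MSTRG.93889 lost), 0 isoforms, 74 genes by usage (47 shared) and 30 lists.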

Other observations

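All tests in this part were chosen after the patterns were seen, except the counts of other splits and the tests of short RNAs against abundant loci and against regional makeup, which were set before their values were seen.

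Short annotated RNAs stood higher in both mutant genotypes. Of 174 tested annotated loci under 350 bp, 151 were higher in homozygous and 157 in heterozygous than in wild-type rats, with median log2 fold changes of 0.62 and 0.54. Without wild-type rat 2 the median in homozygous rats was 1.01: the mean log2 deviation of these loci was -0.03 in that rat, against -0.44 and -0.47 in wild-type rats 1 and 3 and -0.06 in heterozygous rat 2. At an unadjusted p under 0.05, 62 were higher and 0 lower in homozygous rats. Because identical copies share reads, the 174 loci hold 150 distinct sets of counts. The RNA of the signal recognition particle took 4.55 ± 1.91% of all counts in wild-type, 7.49 ± 0.451% in heterozygous and 9.50 ± 1.00% in homozygous rats (SD, n = 3 each). The exact permutation p of homozygous against wild type was 0.1, the smallest that 3 against 3 allows.

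The shift of short RNAs could come from library preparation or from genotype. Leaving out the 10 most abundant and all mitochondrial loci before scaling left the median at 0.62. TMM scaling already trims such loci, so an unchanged median could be foreseen. It does not decide on a few loci taking a varying share of counts. With the cerebellum score as a covariate the median was 0.75, which argues against cerebellar makeup. Across 9 libraries the mean short-RNA level had a Pearson r of -0.29 with fragment length (permutation p = 0.439, Spearman rho 0.05, permutation p = 0.911, and r = -0.436 without the 2 libraries farthest from the median), too weak to decide. Genotype, and any difference between the mutant line and the purchased wild-type rats, stay open as untested.

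Loci shifted the same way in both mutants at an unadjusted p under 0.01 were frequent on chromosome 12, which carries Lrap: 8 of 1092 loci (0.733%) against 81 of 39057 in the genome (0.207%). A candidate explanation is a haplotype that stayed linked to the deletion in the mutant line. Within 20 Mb of Lrap lay 3 of 695 loci, and 0.162 of 10000 circular shifts along the genome gave as many, so linkage cannot be told apart from chance on 3 loci. Some chromosome reached the rate of chromosome 12 in 0.0965 of 2000 shifts, which is what chance placement needs. Named members include Ppp1r35 and Ints1, at 0 CPM in all wild-type rats. Both were low in the mutants as well, and Ints1 was also at 0 CPM in heterozygous rat 1 (1.54 ± 0.874 CPM in homozygous rats).

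Cerebellum and pineal markers differed between libraries of 1 genotype. The 14 cerebellum markers moved together, with a median pairwise Spearman rho of 0.95 across 9 libraries, at percentile 100 of 10000 lists matched on expression, consistent with unequal amounts of cerebellum in the samples. Genotype is argued against as the cause: the cerebellum score ranged over 3.26 log2 units within a genotype, against at most 0.85 between genotype means. The 3 tested pineal markers reached percentile 96.91 (rho 0.70) and are highest in heterozygous rats 2 and 3. This test cannot decide on the amount of pineal gland, since the rest of the list did not pass the filter. By level, the list of 9 pineal genes had a mean log2(CPM + 0.5) of 1.44 and 1.66 in these rats. It was at -0.08 or lower in every other library. Unequal amounts of pineal gland would give such levels, and no further test of this was made.

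Other splits of the libraries show how far chance can be excluded. For the pairwise comparisons 10 splits of 6 libraries exist, too few for a share under 0.05. Where the real count is 0, every split reaches it by construction and the number of splits says nothing of chance. This holds for homozygous against wild type (10 of 10 splits, the highest other at 1628), for isoforms (10 of 10, the highest other at 117) and for allele dose (100 of 100 drawn assignments, the highest other at 8617). For heterozygous against wild type the real 3 was reached by 2 of the 10 splits, the highest other at 2616, and for homozygous against heterozygous the real 1 by 2, the highest other at 1. For isoform usage the real 63 by 2, the highest other at 187, and for lists the real 29 by 3, the highest other at 31. The split of wild-type rats 1 and 2 with homozygous rat 2 from the other 3, which follows cerebellum markers, called the 1628 genes, so the samples carry a structure larger than genotype. For the midpoint 7 of 100 drawn assignments gave at least the real 2, the highest other at 6988, so chance is not excluded.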
